A study of Caenorhabditis elegans with 9 samples.

How the data were processed

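Total RNA of gravid adult Caenorhabditis elegans was measured on Affymetrix arrays. The worms were wild type (N2), metr-1(ok521) mutants or pcca-1(ok2282) mutants, and all were fed the bacterium Comamonas DA1877. Each genotype had 3 biological replicates, which made 9 arrays. Per the labels, RNA was extracted with Trizol and RNeasy columns and turned into biotin-labelled cRNA with a 3' in vitro transcription kit. The deposited values are log2 expression values, 1 per probe set and array, which the authors made with RMA and Affymetrix Expression Console. The versions of both tools, the background settings and any filter are not given in the sources used here. Over the 9 arrays the values ran from 3.13 to 14.9, and none was centred per gene or divided by another array. No further normalization was applied.

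The table held 22625 probe sets. The 77 control probe sets were left out, as were 895 others without a gene and 887 paired with several genes. The remaining 20766 probe sets each had 1 gene. Gene symbols came from the given probe table, updated through the RefSeq gene table of the assembly WBcel235 for 20701 probe sets and kept as they were for 65. That assembly was used for names and for which genes neighbour each other, and for nothing else. Where a gene had several probe sets, the one with the highest mean over the 9 arrays was taken, which concerned 2981 of the 17118 genes tested. Of these genes, 4307 were measured by a probe set whose suffix marks probes that can match several transcripts. The number of arrays limits the precision. The fit had 6 residual degrees of freedom, and the shared estimate of the variance added a prior of 3.96.

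Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings, with statmod 1.5.0 installed). All 9 arrays entered 1 fit with genotype as the only term. The comparisons were metr-1 mutant against wild type, pcca-1 mutant against wild type, and metr-1 against pcca-1 mutant. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 17118 genes, per comparison, in a two-sided test. The words rose, fell and changed are kept for genes that passed. Changes are differences of log2 values with the standard error of the fit, and levels are means with the standard deviation (SD) of 3 arrays.

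Before the data were examined, 31 gene lists, the tests, the comparisons and the rule for naming genes were fixed. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated from the data and with fry. Member counts were made over all genes and adjusted over the list alone. The rule named the members of the lists for the propionate shunt, canonical propionyl-CoA breakdown and the methionine cycle. It added the 10 genes with the largest rise and the 10 with the largest fall whose groups did not overlap. From each other list that passed, or that had at least 3 members past the threshold, it took up to 4 members with the smallest adjusted p. For the overlap it took the 5 genes with the largest mean change in each direction. acdh-2 is named outside the rule in the comparison of the mutants with each other, as are the genes of the closing section that were found by looking.

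Changes shared by the mutants were counted against the number that independent lists would give. Because both comparisons use the same wild-type arrays, the correlation and covariance of the changes were set beside 100 simulations of unchanged groups with shared controls. A split of the wild-type arrays between the comparisons was added after the data were seen. The limma fit was tested on simulated data of 17118 genes, of which 67 had been changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. At a change of 1 it recovered 100% of the changed genes for metr-1 against wild type, 97.0% for pcca-1 against wild type and 98.5% for metr-1 against pcca-1. At 0.5 the shares were 53.7%, 62.7% and 55.2%, and at 2 they were 98.5%, 98.5% and 100%. False calls made up 2.89%, 4.97% and 9.14% of the calls in the same order. The simulated genes were drawn independently of each other and few were changed. In the real data 36.3% of genes passed for metr-1 and 29.8% for pcca-1 against wild type, so these rates need not hold there.

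The alternatives were another variance model, array-median centring, repeated quantile normalization, fits of the compared groups alone, the replicate number as a block, array weights, the median of a gene's probe sets, all probe sets, removal of the dimmest genes, stricter thresholds, and leaving out each array. Ranges of adjusted p over alternatives include the array weights, whose estimation did not converge, and for lists fry, which tests against no change where camera tests against other genes. A fit on genes with unique probe sets alone was chosen after seeing the data. The labels name no batch or scan day, so differences of that kind between genotypes could not be examined.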

Results

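RNA of gravid adult worms was measured in 3 genotypes, each with 3 arrays, on the bacterial diet Comamonas DA1877. The gene metr-1 encodes methionine synthase, and pcca-1 encodes a subunit of propionyl-CoA carboxylase, the enzyme that opens the canonical path of propionate breakdown. Array medians of the log2 expression values were 5.78 ± 0.01 in wild type, 5.6 ± 0.01 in metr-1 mutants and 5.65 ± 0.03 in pcca-1 mutants (SD, n = 3). Across probe sets, which are not independent replicates, arrays of the same genotype correlated at 0.990 to 0.998 and arrays of different genotypes at 0.958 to 0.990. The first component of variation held 65.6% of the variance and the next 19.9%. The actin control, a sign of RNA quality, had a 3' to 5' difference of 0.44 ± 0.04 in wild type, 0.68 ± 0.05 in metr-1 mutants and 0.65 ± 0.05 in pcca-1 mutants (log2, SD, n = 3). The Gapdh control gave 0.04 ± 0.03, -0.17 ± 0.04 and -0.04 ± 0.10 in the same order. The ubiquitin control gave 3.72 ± 0.12, 3.68 ± 0.17 and 3.72 ± 0.04, so the higher difference in the mutants was seen in actin and not in the other controls.

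The deleted genes were read on every array. The pcca-1 probe set gave 10.23, 10.22 and 10.17 on the wild-type arrays, 9.79, 9.98 and 9.67 on the metr-1 arrays, and 5.61, 5.17 and 5.17 on the pcca-1 arrays. In its own mutant pcca-1 fell by 4.89 (SE 0.13) on the log2 scale, with an adjusted p of 1.7e-08. A second pcca-1 probe set read 9.42 ± 0.11 in wild type, 9.20 ± 0.10 in metr-1 mutants and 4.62 ± 0.13 in pcca-1 mutants (SD, n = 3). The metr-1 probe set gave 9.57, 9.45 and 9.73 on the wild-type arrays, 9.80, 9.86 and 9.92 on the metr-1 arrays, and 9.59, 9.58 and 9.54 on the pcca-1 arrays. In its own mutant metr-1 rose by 0.28 (SE 0.09), with an adjusted p of 0.027, which ran from 0.0015 to 0.17 over the alternatives and missed the threshold without wild-type replicate 1 (0.074), wild-type replicate 2 (0.10), metr-1 replicate 2 (0.051) or metr-1 replicate 3 (0.070). Where this probe set lies relative to the deleted part is not given in the sources used here, so it checks nothing about the metr-1 labels.

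**Figure D1:**
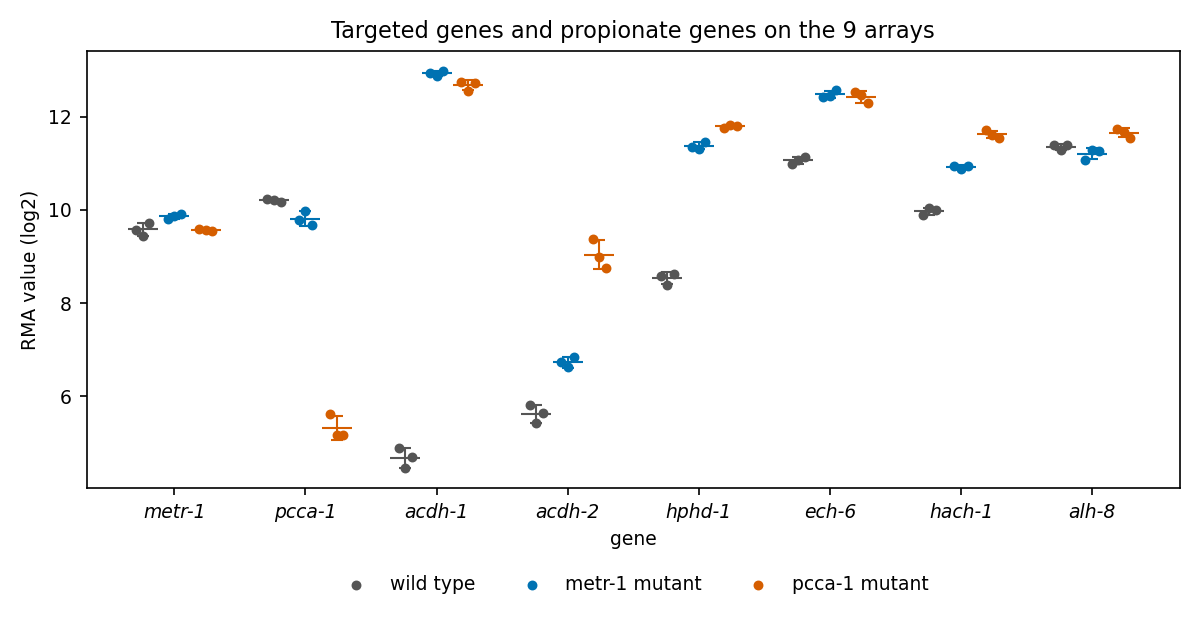
Log2 RMA values (vertical axis) of the deleted genes, the shunt genes and acdh-2 (horizontal axis) on the 9 arrays, with a point for each array, a horizontal mark for the mean of 3 arrays and a bar for the SD. The mean of acdh-1 lay at 4.68 in wild type, 12.93 in metr-1 and 12.68 in pcca-1 mutants, and that of pcca-1 at 5.32 in its own mutant.

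Metr-1 mutant against wild type asks what loss of methionine synthase changes on this diet. The gene acdh-1, an acyl-CoA dehydrogenase of the propionate shunt, went from 4.68 ± 0.22 to 12.93 ± 0.05 (SD, n = 3). It rose by 8.25 (SE 0.11), with an adjusted p of 4.4e-11. Its wild-type level is close to 4.36, under which genes were taken as dim, so the size of this rise is uncertain and possibly too small. Further shunt genes rose as well, hphd-1 by 2.83 (SE 0.08), ech-6 by 1.41 (SE 0.09) and hach-1 by 0.95 (SE 0.08). The largest measured falls were those of pud-3, which fell by 8.24 (SE 0.16), of pud-4, which fell by 8.18 (SE 0.10), and of nspg-7.2, which fell by 5.37 (SE 0.08). In the mutant pud-4 read 3.92, under that level, and pud-3 4.72, so these sizes and their order are uncertain as well. Other large changes were rises of clc-24 by 4.58 (SE 0.17) and of the C-type lectin gene clec-47 by 4.57 (SE 0.28), and a fall of the acid ceramidase gene asah-1, which fell by 4.03 (SE 0.21).

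Of the 5 propionate shunt genes, 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 3.6e-04; adjusted p = 0.33 with an estimated correlation). The remaining one, alh-8, read -0.15 (SE 0.09) with an adjusted p of 0.24. In canonical propionyl-CoA breakdown, 3 of 6 genes rose and 2 fell (adjusted p = 0.78), with mmaa-1 higher by 0.81 (SE 0.10) and pccb-1 lower, by a change of -0.41 (SE 0.09). The fall of pcca-1 in this mutant, -0.39 (SE 0.13), did not pass without wild-type replicate 1 (0.094), 2 (0.091) or 3 (0.072), without metr-1 replicate 1 (0.096) or 3 (0.10), or with array-median centring (0.15), and the adjusted p ran from 3.3e-04 to 0.15 over its alternatives. In the methionine cycle and folate list, 6 of 12 genes rose and 3 fell (adjusted p = 0.18); the rises include metr-1 itself, which is mutated here and whose call is lost under several alternatives. The methionine synthase reductase gene mtrr-1 rose by 1.17 (SE 0.09), mthf-1 by 0.61 (SE 0.11), mel-32 by 0.75 (SE 0.08) and the thymidylate synthase gene tyms-1 by 1.77 (SE 0.08). The S-adenosylmethionine synthetase genes sams-1 and sams-5 fell, with changes of -1.08 (SE 0.20) and -1.27 (SE 0.14), and the methyltransferase gene pmt-1 fell by 0.86 (SE 0.10).

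Sulfur and lipid genes moved in both directions. In transsulfuration and sulfide handling, 6 of 15 genes rose and 5 fell: cbs-1, which encodes cystathionine beta-synthase, fell by 3.09 (SE 0.18), cth-1 fell by 1.77 (SE 0.19) and rhy-1 rose by 1.60 (SE 0.10). Of 13 nuclear hormone receptors, 7 rose and 1 fell, with nhr-114 higher by 2.45 (SE 0.12) and nhr-49 by 0.57 (SE 0.11). In fatty acid synthesis and desaturation, 4 of 20 rose and 5 fell, with the desaturase gene fat-5 higher by 2.85 (SE 0.11) and fat-3 at -1.11 (SE 0.19). In beta-oxidation, 3 of 20 rose and 10 fell, with acdh-8 at -3.22 (SE 0.18) and the lipase gene lipl-4 at 1.61 (SE 0.12). Of 5 yolk protein genes 1 fell, and of 11 genes of branched-chain amino acid breakdown 3 fell, acdh-9 by a change of -0.59 (SE 0.11). None of these 6 lists passed camera (adjusted p = 0.86, 0.087, 0.86, 0.12, 0.69 and 0.12). The median and mean differed in sign for transsulfuration (0.01 and -0.05) and fatty acid synthesis (-0.19 and 0.15). Array-median centring adds about the same shift to all genes, so it moves medians through 0 here and below without a change relative to other genes. With it, the yolk and branched-chain medians turned from -0.03 and -0.17 to 0.15 and 0.01, and beta-oxidation passed (adjusted p = 0.026, with 0.0034 to 0.48 over its alternatives, the lowest from fry, which tests against no change).

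Germline markers changed beside an actin 3' to 5' difference of 0.68 against 0.44 in wild type, which the Gapdh and ubiquitin controls did not share. Of 23 sperm genes, 22 fell, and 22 when adjusted over the list alone. The major sperm protein gene msp-142 fell by 3.19 (SE 0.12) and the sperm phosphatase gene gsp-4 fell by 2.93 (SE 0.11). The list median lay at -2.10 relative to the median of all genes (camera adjusted p = 5.2e-18; adjusted p = 0.33 with an estimated correlation). Of 24 oocyte and eggshell genes, 20 rose, and 23 when adjusted over the list alone, among them egg-3 by 1.27 (SE 0.09) and nos-2 by 1.0 (SE 0.08). Their relative median was 0.75 (adjusted p = 7.4e-08; adjusted p = 0.48 with an estimated correlation). Of 26 mitotic germline and meiosis genes, 11 rose, with mcm-5 at 0.76 (SE 0.09), and of 27 zygotic embryo genes 7 rose and 1 fell, with tbx-9 at 0.91 (SE 0.10). Adjusted over the list alone, 13 and 5 rose. Both passed (adjusted p = 0.016 and 0.037; adjusted p = 0.48 and 0.36 with an estimated correlation), the first not with array-median centring (0.058, with 7.3e-04 to 0.48 over its alternatives).

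Changes of cuticle, muscle and nerve genes stand beside the same actin difference of 0.68 against 0.44. Of 128 collagens, 80 fell and 1 rose, or 83 and 1 when adjusted over the list alone; col-39 fell by 3.66 (SE 0.12) and col-149 fell by 3.20 (SE 0.19). Of 21 muscle markers, 13 fell and 1 rose, with the troponin gene tni-1 at -1.43 (SE 0.14). Of 26 neuron markers, 14 fell and 2 rose, with the neuropeptide gene flp-9 at -1.44 (SE 0.13). Adjusted over the list alone, 13 and 14 fell. Relative medians were -0.47, -0.70 and -0.35 (camera adjusted p = 2.6e-14, 0.0012 and 0.0029; adjusted p = 0.48, 0.39 and 0.39 with an estimated correlation). Of 15 hypodermis and seam genes, 6 fell and 3 rose (adjusted p = 0.069), and the transcription factor gene elt-3 fell by 1.42 (SE 0.13). Of 22 intestine markers, 9 fell and 2 rose (adjusted p = 0.065), with the intermediate filament gene ifb-2 at -1.29 (SE 0.11); the list median turned from -0.16 to 0.01 with array-median centring. Of 31 moulting and larval cuticle genes, 6 fell and 2 rose (adjusted p = 0.22), with dpy-5 at -0.90 (SE 0.12); that median turned from -0.09 to 0.09 with centring.

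Among defence and stress lists, 15 of 33 innate immune effectors fell and 6 rose, and as many when adjusted over the list alone: dod-22 fell by 3.01 (SE 0.13) and cnc-4 rose by 1.83 (SE 0.13). Of 40 glutathione S-transferases, 15 fell and 4 rose, or 16 and 4 when adjusted over the list alone, and gst-10 fell by 2.89 (SE 0.12). Of 64 UDP-glucuronosyltransferases, 24 fell and 7 rose, and as many when adjusted over the list alone; ugt-9 fell by 1.90 (SE 0.13), while the list median turned from -0.09 to 0.09 with array-median centring. Of 9 heat shock genes, 6 rose and 1 fell, and as many when adjusted over the list alone, with hsp-12.3 at 2.21 (SE 0.16) and hsf-1 at 0.96 (SE 0.12). Relative medians were -0.29, -0.27, -0.12 and 0.92, and the 4 lists passed (camera adjusted p = 0.019, 0.0012, 0.039 and 0.031; adjusted p = 0.48 for each with an estimated correlation). The heat shock list did not pass with centring (0.12, with 8.3e-04 to 0.48 over its alternatives, the lowest from fry, which tests against no change).

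Proteasome subunits, with 12 of 33 that rose, and cytosolic ribosomal proteins, with 9 of 75 that rose and 2 that fell, had higher medians (0.18 and 0.07 relative to all genes). Of all 17118 genes 3177 rose, a larger share than among the ribosomal genes. Adjusted over the list alone, 12 proteasome genes rose, while 0 ribosomal genes rose and 2 fell in limma (23 in either direction at an unadjusted p under 0.05). Both lists passed (adjusted p = 0.0065 and 0.031; adjusted p = 0.48 for each with an estimated correlation). The proteasome genes rpn-12 and rpt-1 rose by 0.45 (SE 0.08) and 0.40 (SE 0.10), and the ribosomal genes rpl-23A.1 and rpl-11.2 fell, with changes of -0.75 (SE 0.09) and -0.69 (SE 0.09). ER stress had 7 of 16 genes that rose and 3 that fell, with pek-1 at 0.93 (SE 0.18). The mitochondrial stress list had 2 of 16 that rose and 2 that fell, with atfs-1 at 0.68 (SE 0.14). Oxidative stress targets had 6 of 20 that rose and 5 that fell, with sip-1 at 0.78 (SE 0.11). Of 73 cytochrome P450 genes 9 rose and 19 fell, with cyp-33C8 at 2.49 (SE 0.13), and of 220 C-type lectins 20 rose and 30 fell, with clec-151 at -2.53 (SE 0.08). The respiratory chain had 3 of 23 that rose and 2 that fell, with cox-11 at 0.46 (SE 0.11). These 6 lists did not pass, with adjusted p from 0.12 for cytochrome P450 to 0.86 for C-type lectins. Among them, the mitochondrial stress median (0.04) and mean (-0.03) differed in sign, the C-type lectins had a median of 0.03 and were tested as lower, and the oxidative stress list had a median of -0.01 and was tested as higher. With centring, the medians of oxidative stress, cytochrome P450 and respiratory chain genes turned positive, at 0.17, 0.13 and 0.06.

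In all, 6221 genes passed in limma, 3177 higher and 3044 lower in the metr-1 mutant. Changes of at least 2-fold made up 1471, of which 356 were higher and 1115 lower. Array-median centring moved the median change of all genes from 0.04 to 0.21, and 9876 genes then passed, 7539 higher and 2337 lower; at 2-fold or more it gave 688 higher and 890 lower. Intestine markers and hypodermis genes then passed as lower than other genes (0.042 and 0.049, with 0.0076 to 0.48 and 6.7e-04 to 0.39 over their alternatives, both lowest from fry), besides beta-oxidation. The intestine and hypodermis medians relative to all genes stayed at -0.20 and -0.27, so these calls do not come from a larger relative median. Without metr-1 replicate 2, 9 lists passed in place of 14, and the lists lost were UDP-glucuronosyltransferases (0.094), ribosomal proteins (0.14), proteasome (0.060), mitotic germline (0.075) and zygotic embryo (0.075). Without wild-type replicate 2, UDP-glucuronosyltransferases (0.053), ribosomal proteins (0.051) and zygotic embryo genes (0.051) missed and intestine markers passed (0.047). UDP-glucuronosyltransferases also missed without wild-type replicate 3 (0.056) or metr-1 replicate 1 (0.052), zygotic embryo genes without metr-1 replicate 3 (0.060), and hypodermis genes passed without wild-type replicate 1 (0.0499).

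Pcca-1 mutant against wild type asks what loss of the canonical propionate path changes. The shunt gene acdh-1 went from 4.68 ± 0.22 to 12.68 ± 0.11 (SD, n = 3). It rose by 8.0 (SE 0.11), with an adjusted p of 1.2e-10, and hphd-1 rose by 3.25 (SE 0.08). The size of the acdh-1 rise is again limited by the dim wild-type level. The acyl-CoA synthetase gene acs-2 rose by 4.5 (SE 0.19), acdh-2 by 3.41 (SE 0.16), dod-3 by 4.40 (SE 0.41) and the infection response gene irg-2 by 3.59 (SE 0.29). The suffix of the acdh-2 probe set marks probes that can match several transcripts. A second acdh-2 probe set without it read 3.68 ± 0.13 in wild type and 7.75 ± 0.14 in pcca-1 mutants (SD, n = 3). After pcca-1 itself the largest falls were in nspg-7.2, which fell by 4.43 (SE 0.08), and the sperm gene spe-11, which fell by 3.09 (SE 0.18).

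All 5 propionate shunt genes rose, and 5 when adjusted over the list alone (camera adjusted p = 3.7e-07; adjusted p = 0.18 with an estimated correlation). They included hach-1 at 1.64 (SE 0.08) and ech-6 at 1.36 (SE 0.09), while the smallest rise, of alh-8 at 0.30 (SE 0.09), did not pass without wild-type replicate 1 (0.055) or 2 (0.093) or pcca-1 replicate 1 (0.082) or 2 (0.079), or with the replicate number as a block (0.056), with 0.0027 to 0.093 over its alternatives. Of the 6 canonical genes, 2 fell, pcca-1 and pccb-1. The fall of pccb-1, -0.39 (SE 0.09), did not pass with the median of a gene's probe sets (0.072, with 8.0e-04 to 0.072 over its alternatives), and mmaa-1 rose by 0.32 (SE 0.10), a rise that did not pass without any 1 wild-type array (0.069, 0.11 and 0.057) or without pcca-1 replicate 1 (0.092) or 2 (0.097), or with repeated quantile normalization (0.065), with 0.0015 to 0.11 over its alternatives. That list did not pass (adjusted p = 0.64), and its median of 0.07, which turned negative with repeated quantile normalization, and mean of -0.76 differed in sign. In the methionine cycle and folate list, 5 of 12 genes fell and 2 rose (adjusted p = 0.20). The genes sams-1, sams-5 and pmt-2 fell, with changes of -1.57 (SE 0.20), -1.54 (SE 0.14) and -0.64 (SE 0.12), while tyms-1 rose by 1.56 (SE 0.08) and mtrr-1 by 0.46 (SE 0.09).

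Lipid and sulfur genes again moved in both directions. In fatty acid synthesis, 5 of 20 fell and 2 rose, with the desaturase gene fat-7 at -1.81 (SE 0.24) and the fatty acid synthase gene fasn-1 at -1.02 (SE 0.21). In beta-oxidation, 4 of 20 rose and 4 fell, with acdh-8 at -2.72 (SE 0.18) and cpt-5 at -0.79 (SE 0.14) beside the rise of acs-2. In transsulfuration and sulfide handling, 6 of 15 rose and 3 fell, with the sulfide oxidation gene sqrd-1 at 1.34 (SE 0.18) and cbs-1 at -1.72 (SE 0.18). Of 13 nuclear hormone receptors, 5 rose and 3 fell, with nhr-114 at -0.83 (SE 0.12) and nhr-64 at 0.50 (SE 0.12). Of 11 branched-chain genes, 2 rose and 3 fell, with kat-1 at 0.35 (SE 0.07) and bcat-1 at -0.50 (SE 0.10), and of 5 yolk protein genes 2 rose. These 6 lists did not pass (adjusted p = 0.53, 0.65, 0.73, 0.64, 0.95 and 0.064). The transsulfuration median of -0.02 and mean of 0.06 differed in sign, and with array-median centring the medians of fatty acid synthesis, transsulfuration and branched-chain breakdown turned positive, at 0.06, 0.11 and 0.12.

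Sperm markers changed here too, beside an actin 3' to 5' difference of 0.65 against 0.44 in wild type, which the Gapdh and ubiquitin controls did not share. Of 23 markers 22 fell, and 22 when adjusted over the list alone, with gsp-3 at -2.77 (SE 0.13) and msp-142 at -2.39 (SE 0.12). The list median lay at -2.01 relative to all genes (camera adjusted p = 4.6e-19; adjusted p = 0.18 with an estimated correlation). Of 24 oocyte and eggshell genes, 10 rose, and 10 when adjusted over the list alone, with egg-3 at 0.93 (SE 0.09) and nos-2 at 0.74 (SE 0.08). Their relative median was 0.33 (adjusted p = 2.1e-04; adjusted p = 0.84 with an estimated correlation). Of 26 mitotic germline genes 2 rose and 1 fell, and of 27 zygotic embryo genes 6 rose and 1 fell (adjusted p = 0.53 and 0.067); mcm-5 rose by 0.57 (SE 0.09) and pes-10 by 0.79 (SE 0.10).

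Changes of collagens stand beside the same actin difference of 0.65 against 0.44. Of 128, 97 fell and 1 rose, or 100 and 2 when adjusted over the list alone, with col-149 at -2.87 (SE 0.19) and col-39 at -2.57 (SE 0.12). Of 21 muscle markers, 11 fell and 1 rose, with the troponin gene mup-2 at -0.95 (SE 0.11). Of 26 neuron markers 11 fell, with unc-25, which encodes glutamate decarboxylase, at -1.07 (SE 0.12). Adjusted over the list alone, 11 and 13 fell. Relative medians were -0.62, -0.29 and -0.28 (camera adjusted p = 1.4e-21, 0.0016 and 2.1e-04; adjusted p = 0.34, 0.34 and 0.26 with an estimated correlation). Of 15 hypodermis genes, 6 fell and 1 rose (adjusted p = 0.076), with elt-3 at -1.72 (SE 0.13). Of 31 moulting genes, 9 fell and 5 rose (adjusted p = 0.64), with sqt-2 at -0.90 (SE 0.10) and wrt-10 at 1.44 (SE 0.22). Of 22 intestine markers, 8 fell and 6 rose (adjusted p = 0.83), with the ferritin gene ftn-1 at 2.06 (SE 0.31) and ifc-2 at -0.63 (SE 0.10). Medians and means differed in sign for moulting (-0.01 and 0.02) and intestine genes (-0.01 and 0.05), whose medians turned to 0.12 and 0.12 with centring.

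Cytosolic ribosomal proteins passed, with 19 of 75 that rose, and 16 when adjusted over the list alone, among them rps-9 at 0.29 (SE 0.07) (adjusted p = 1.2e-04; adjusted p = 0.34 with an estimated correlation). DAF-16 and oxidative stress targets passed narrowly, with 6 of 20 that rose, and 6 when adjusted over the list alone, among them the superoxide dismutase gene sod-1 at 0.45 (SE 0.08) (adjusted p = 0.048; adjusted p = 0.26 with an estimated correlation). Their relative medians were 0.12 and 0.21. Of 33 immune effectors, 12 rose and 9 fell, with cnc-4 at 3.19 (SE 0.13) and clec-41 at -1.1 (SE 0.11). Of 9 heat shock genes, 5 rose and 1 fell, with hsp-70 at 2.03 (SE 0.20). Of 73 cytochrome P450 genes, 14 rose and 13 fell, with cyp-13A2 at -1.45 (SE 0.11). UDP-glucuronosyltransferases had 11 of 64 that rose and 11 that fell, with ugt-9 at -2.05 (SE 0.13) and ugt-53 at 2.05 (SE 0.16). Glutathione S-transferases had 5 of 40 that rose and 16 that fell, with gst-38 at -1.58 (SE 0.16). Of 220 C-type lectins, 17 rose and 18 fell, with clec-266 at 3.21 (SE 0.18). Proteasome subunits had 6 of 33 that rose, led by rpn-12 at 0.36 (SE 0.08), and the respiratory chain 3 of 23, led by cox-11 at 0.49 (SE 0.11). ER stress had 2 of 16 that rose and 4 that fell, with pek-1 at 1.43 (SE 0.18), and mitochondrial stress 1 of 16 that rose and 1 that fell. The last 10 lists did not pass, with adjusted p from 0.10 for glutathione S-transferases to 0.99 for mitochondrial stress. With array-median centring the medians of cytochrome P450, UDP-glucuronosyltransferase, glutathione S-transferase, C-type lectin, mitochondrial stress and respiratory chain genes turned from negative to positive, and the median and mean differed in sign for cytochrome P450 (0.00 and 0.02) and the respiratory chain (-0.03 and 0.01).

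In all, 5106 genes passed in limma, 2609 higher and 2497 lower in the pcca-1 mutant. Changes of at least 2-fold made up 1187, of which 277 were higher and 910 lower. Array-median centring moved the median change of all genes from 0.02 to 0.15, and 6596 genes then passed, 4607 higher and 1989 lower; at 2-fold or more it gave 402 higher and 766 lower. Glutathione S-transferases and hypodermis genes then passed as lower than other genes (0.042 and 0.042, with 0.031 to 0.86 and 4.4e-04 to 0.29 over their alternatives, the latter lowest from fry). Their medians relative to all genes stayed at -0.12 and -0.19, so these calls do not come from a larger relative median. The oxidative stress list missed without wild-type replicate 3 (0.10), metr-1 replicate 2 (0.054), metr-1 replicate 3 (0.051) or pcca-1 replicate 2 (0.052), and with centring (0.083, with 4.4e-04 to 0.26 over its alternatives, the lowest from fry, which tests against no change). Without pcca-1 replicate 1, the yolk (0.048), glutathione S-transferase (0.031), proteasome (0.048) and zygotic embryo lists (0.039) passed as well. The yolk list also passed without metr-1 replicate 1 (0.048), and the zygotic embryo (0.047) and hypodermis lists (0.045) without pcca-1 replicate 3.

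Metr-1 against pcca-1 mutant tests directly where the effects of the mutations differ. The shunt gene acdh-1 differed by 0.26 (SE 0.11), with an adjusted p of 0.24, while acdh-2 was lower in the metr-1 mutant by a difference of -2.31 (SE 0.16). The second acdh-2 probe set read 5.79 ± 0.22 in metr-1 and 7.75 ± 0.14 in pcca-1 mutants (SD, n = 3). The nuclear hormone receptor gene nhr-114 was higher in the metr-1 mutant, at 9.74 ± 0.13 against 6.46 ± 0.24 (SD, n = 3), a difference of 3.28 (SE 0.12). The methionine sulfoxide reductase gene msra-1 was higher by 3.47 (SE 0.17) and clc-24 by 4.54 (SE 0.17). Differences were negative for pud-3 at -5.49 (SE 0.16), for the lipase genes lipl-1 and lipl-2 at -4.40 (SE 0.32) and -4.68 (SE 0.35), for asah-1 at -4.18 (SE 0.21) and for the monooxygenase gene fmo-2 at -4.62 (SE 0.77).

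Of 12 methionine cycle and folate genes, 5 were higher in the metr-1 mutant and 1 was lower, or 9 and 1 when adjusted over the list alone. The list holds metr-1, which is mutated in 1 of the strains and did not pass over all genes here. The genes mthf-1, mel-32, pmt-2 and mtrr-1 were higher by 0.97 (SE 0.11), 0.75 (SE 0.08), 0.75 (SE 0.12) and 0.71 (SE 0.09), and pmt-1 differed by -0.64 (SE 0.10). The relative median was 0.53 (camera adjusted p = 4.3e-06; adjusted p = 0.15 with an estimated correlation). In the propionate shunt, 3 of 5 genes were lower in the metr-1 mutant, and 3 when adjusted over the list alone, with hach-1 at -0.69 (SE 0.08). In canonical breakdown, 2 of 6 were higher, and 2 when adjusted over the list alone, mmaa-1 by 0.49 (SE 0.10) and the deleted gene pcca-1 by 4.5 (SE 0.13). The canonical list holds the gene deleted in the pcca-1 mutant. Its mean was 0.86 but its median 0.12, so its shift mostly restates the deletion. These lists passed (adjusted p = 0.025 and 0.015; adjusted p = 0.35 and 0.19 with an estimated correlation).

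Fat oxidation and defence lists differed between the mutants through a part of their members. In beta-oxidation, 9 of 20 were lower and 1 higher, or 12 and 1 when adjusted over the list alone, with acs-2 at -2.87 (SE 0.19), the peroxisomal oxidase gene acox-3 at -2.06 (SE 0.20) and the lipase gene lipl-4 at 1.59 (SE 0.12). Of 33 immune effectors, 17 were lower and 2 higher, or 20 and 4 when adjusted over the list alone, with dod-22 at -2.02 (SE 0.13), clec-67 at -2.21 (SE 0.15) and the lysozyme gene lys-5 at 3.00 (SE 0.22). Relative medians were -0.51 and -0.60 (camera adjusted p = 4.3e-06 and 1.0e-10; adjusted p = 0.15 for both with an estimated correlation). Of 20 oxidative stress targets 4 were lower, of 40 glutathione S-transferases 9 were lower and 1 higher, and of 5 yolk protein genes 1 was lower, vit-1 at -1.1 (SE 0.10). Adjusted over the list alone, 7, 10 and 3 were lower. The catalase gene ctl-2 differed by -0.87 (SE 0.12), and gst-10, a member of both of the first lists, by -2.84 (SE 0.12). All 3 passed (adjusted p = 0.0058, 4.3e-05 and 4.9e-04; adjusted p = 0.15, 0.44 and 0.19 with an estimated correlation).

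Sperm markers were lower in the metr-1 than in the pcca-1 mutant in 10 of 23 cases, or 12 when adjusted over the list alone, with msp-33 at -0.88 (SE 0.12) and msp-142 at -0.80 (SE 0.12). Of 24 oocyte genes 0 passed in limma over all genes (10 at an unadjusted p under 0.05), with egg-3 at 0.34 (SE 0.09), and 7 were higher when adjusted over the list alone. Of 26 mitotic germline genes 0 passed in limma either way (2 unadjusted). Relative medians were -0.42, 0.38 and 0.25 (camera adjusted p = 6.8e-07, 9.5e-07 and 0.0020; adjusted p = 0.30, 0.44 and 0.44 with an estimated correlation). Of 22 intestine markers, 6 were lower and 2 higher, or 10 and 2 when adjusted over the list alone, with ifc-2 at -0.92 (SE 0.10) and ifb-2 at -0.83 (SE 0.11) (adjusted p = 0.0020; adjusted p = 0.36 with an estimated correlation). The 3' to 5' differences of the metr-1 and pcca-1 mutants were 0.68 and 0.65 for actin, -0.17 and -0.04 for Gapdh, and 3.68 and 3.72 for ubiquitin.

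Further lists passed with small shifts. Cytochrome P450 genes, with 13 of 73 lower and 3 higher and cyp-34A9 at -1.36 (SE 0.11), were tested as lower, with a mean of -0.19 but a median of 0.00, which differs in sign and turned negative with repeated quantile normalization. UDP-glucuronosyltransferases had 15 of 64 lower and 10 higher, with ugt-53 at -2.45 (SE 0.16) and ugt-63 at 2.82 (SE 0.24). Collagens had 5 of 128 higher and 3 lower, with col-39 at -1.09 (SE 0.12). Of 11 branched-chain genes 1 was lower, acdh-9 at -1.0 (SE 0.11). Ribosomal proteins had 2 of 75 lower, rpl-11.2 at -0.64 (SE 0.09) and rpl-23A.1 at -0.65 (SE 0.09), and their median turned from -0.04 to 0.01 with array-median centring. Of 33 proteasome subunits 0 passed in limma (0 at an unadjusted p under 0.05), and their relative median was 0.09. The 6 lists had adjusted p = 0.030, 0.044, 0.021, 0.049, 0.013 and 0.025, against adjusted p = 0.44, 0.49, 0.75, 0.44, 0.44 and 0.49 with an estimated correlation. Adjusted over the list alone, 15, 18, 3, 2, 2 and 0 were lower and 3, 14, 5, 1, 0 and 0 higher.

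The other 13 lists did not pass. Of 13 nuclear hormone receptors 2 were higher and 1 lower, with nhr-64 at -0.62 (SE 0.12) beside nhr-114. In fatty acid synthesis 4 of 20 were higher and 3 lower, with fat-7 at 3.13 (SE 0.24), fat-5 at 2.48 (SE 0.11) and fat-3 at -1.54 (SE 0.19). In transsulfuration 2 of 15 were higher and 3 lower, with rhy-1 at 1.0 (SE 0.10) and cbs-1 at -1.36 (SE 0.18). C-type lectins had 9 of 220 higher and 14 lower, with clec-3 at 2.63 (SE 0.23), and moulting genes 1 of 31 higher and 2 lower. Heat shock genes had 2 of 9 higher, ER stress 1 of 16 higher, mitochondrial stress 1 of 16 lower, zygotic embryo 1 of 27 lower, muscle 1 of 21 lower, neuron 1 of 26 higher and hypodermis 1 of 15 higher. The respiratory chain had 0 of 23 that passed in limma and 1 at an unadjusted p under 0.05. Adjusted p ran from 0.051 for the respiratory chain to 0.93 for hypodermis. The median and mean differed in sign for mitochondrial stress, moulting, neuron and hypodermis genes, and the medians of mitochondrial stress and hypodermis genes changed sign under a scaling.

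In all, 1284 genes passed in limma, 345 higher and 939 lower in the metr-1 than in the pcca-1 mutant. Differences of at least 2-fold made up 400, of which 98 were higher and 302 lower. Without metr-1 replicate 3 the count was 2211. With the replicate number as a block 16 of the 18 lists passed. With array-median centring the branched-chain and ribosomal lists missed (0.058 and 0.078, with 0.015 to 0.44 and 5.1e-04 to 0.44 over their alternatives). Lists that missed without metr-1 replicate 1 were collagens (0.066), proteasome (0.064), branched-chain (0.081) and UDP-glucuronosyltransferases (0.067). Without metr-1 replicate 2 they were cytochrome P450 (0.092), UDP-glucuronosyltransferases (0.18), proteasome (0.31) and mitotic germline (0.056), and the respiratory chain passed (0.0040). Without metr-1 replicate 3 they were canonical breakdown (0.0504), branched-chain (0.17), collagens (0.33) and ribosomal proteins (0.17), and ER stress and muscle genes passed (0.017 for both). Without pcca-1 replicate 1 they were branched-chain (0.14), cytochrome P450 (0.086) and proteasome (0.17), and without pcca-1 replicate 2 branched-chain (0.087). Without pcca-1 replicate 3 they were collagens (0.59), ribosomal proteins (0.16), cytochrome P450 (0.052) and UDP-glucuronosyltransferases (0.052), and nuclear hormone receptors passed (0.037). The branched-chain and UDP-glucuronosyltransferase lists also missed without wild-type replicate 1 (0.055 for both), 2 (0.052) or 3 (0.051).

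**Figure D2:**
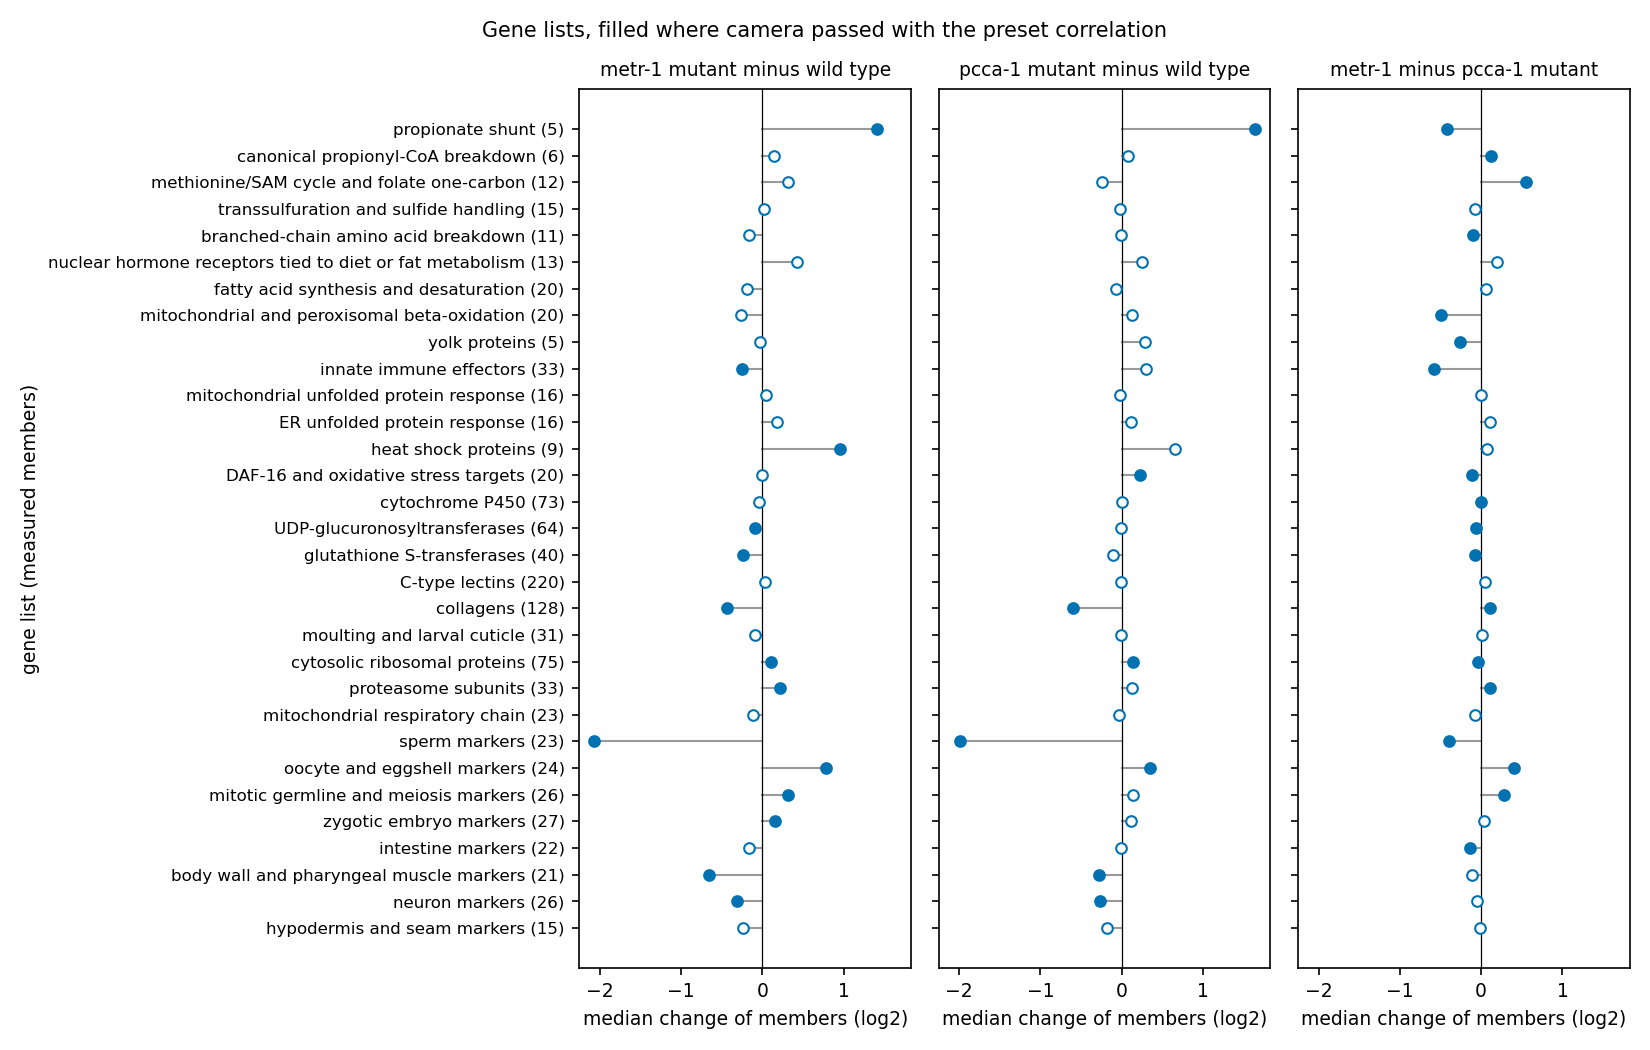
Median change (log2, horizontal axis) of the measured members of each of the 31 gene lists (vertical axis) in the 3 comparisons, with filled points where camera passed with the preset correlation (14, 8 and 18 lists). With an estimated correlation camera passed 0 in each, with 3, 5 and 6 lists at an unadjusted p under 0.05, while fry passed 20, 13 and 12; sperm markers lay at -2.07 and -1.99 in the mutants, and several medians near 0 change sign with array-median centring, which shifts all genes alike and leaves relative medians as they are.

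The changes shared by both mutants were counted against independent lists. Of genes past the threshold in both, 1980 rose in both (484 by independence), 2135 fell in both (444) and 144 went in opposite directions (927). The largest shared rises were those of acdh-1, of F15E6.4, which rose by 2.70 (SE 0.12) in the metr-1 and 4.23 (SE 0.12) in the pcca-1 mutant, and of clec-47, acs-2 and hphd-1. The largest shared falls were those of pud-4 and pud-3, with changes of -2.85 (SE 0.10) and -2.75 (SE 0.16) in the pcca-1 mutant, and of nspg-7.2, Y106G6A.4 and C27D6.3. Of the sperm markers, 22 of 23 fell in both mutants, and of the collagens 77 of 128.

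Both comparisons use the same 3 wild-type arrays, which alone makes their changes correlate. Across genes, which are not independent replicates, the changes correlated at r = 0.80, against 0.50 in simulations of unchanged groups with shared controls. The covariance was 0.284 against 0.00772, and 78% of genes had the same sign against 66.7%. With the wild-type arrays split 1 and 2, so that the comparisons share none, the 6 ways to do so gave r = 0.71 to 0.82, a covariance of 0.262 to 0.291 and 69.4% to 74.4% of genes with the same sign. This split removes only the noise of single wild-type arrays. A trait common to all 3 of them still enters both comparisons alike. Examples are the age at harvest, which was not tested, and the actin 3' to 5' difference. It was 0.44 in wild type, 0.68 in metr-1 and 0.65 in pcca-1 mutants. The gene counts above still share their controls, so part of their excess over independence may come from the shared arrays. Of the 144 opposite genes, 109 fell in the metr-1 and rose in the pcca-1 mutant, and 35 did the reverse. This count of 144 was 85 without wild-type replicate 2, 85 without wild-type replicate 3, 95 without metr-1 replicate 1 and 93 without pcca-1 replicate 2.

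**Figure D3:**
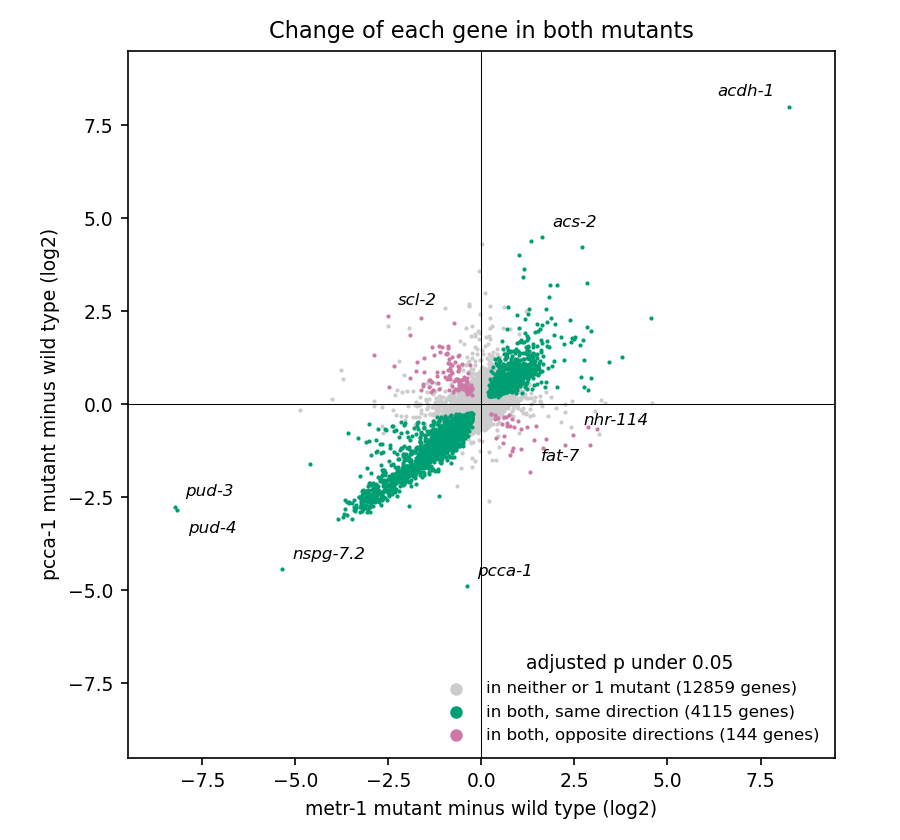
Change of each of the 17118 genes in the metr-1 (horizontal axis) and the pcca-1 mutant (vertical axis) against wild type, both log2, with 1 point per gene colored by whether it passed in both mutants and in which directions. The gene acdh-1 lies at 8.25 and 8.0, pud-4 at -8.18 and -2.85, and 144 genes passed in opposite directions.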

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

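The tests of shared probes, moulting larvae, single arrays, intestinal RNA and the pud genes were chosen only after the results were seen. Those of males and of other splits of the arrays were set before. The intervals given with medians below come from resampling the genes of a list, not the arrays. They treat genes as independent and hold no spread between arrays, so they are not intervals of the genotype effect.

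Genes stood out where the mutants moved in opposite directions by at least 2-fold, which held for 17 genes; their difference between the mutants follows from this selection. In 12 of them the metr-1 mutant was lower. The differences, metr-1 minus pcca-1 on the log2 scale, were -4.90 for scl-2, -4.21 for F42A10.7, -3.94 for asm-3, -3.77 for cyp-37B1, -3.39 for adh-1 and -2.86 for aqp-1. They were -2.85 for fmo-1, -2.76 for C08F11.13, -2.70 for pgp-5, -2.59 for F41E6.5, -2.59 for T16G1.6 and -2.51 for F54B8.4. In the other 5 genes the metr-1 mutant was higher, with 4.03 for Y41C4A.32, 3.33 for warf-1, 3.13 for fat-7, 2.82 for asp-12 and 2.26 for clc-11. Of the 1782 probe sets without a single gene, which entered no comparison, 145 changed by at least 2-fold past the threshold in the metr-1 mutant, 28 higher and 117 lower than in wild type, and 138 in the pcca-1 mutant, 34 higher and the rest lower.

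Sperm markers fell in both mutants, 22 of 23 in each. Probes shared within the major sperm protein family as the whole cause would not account for falls of 9 markers with unique probe sets. The symbols of these 9 do not begin with msp or msd. Of these, 9 fell in both mutants, with medians of -1.26 (-3.30 to -0.44) and -1.05 (-2.50 to -0.53, 95% bootstrap intervals over genes). A first bound, an upper limit under -0.5 in both, was missed by the metr-1 mutant and replaced by this count after the test ran. The 9 markers belong to the flagged list itself, so their falls are no separate test. Males in the wild-type samples stay open: 4 of 11 male neuron markers lay above 4.36, the level under which genes were taken as dim, and had medians of 0.025 (-0.27 to 0.15) in the metr-1 and -0.07 (-0.13 to -0.03) in the pcca-1 mutant, which met the bound set before, but levels of 4.52 to 5.37, under the median gene at 5.84, leave them too near the floor for that bound to decide. Moulting larvae in wild type stay open as well, since 27 of 31 moulting genes had a median of -0.19 (-0.31 to 0.06) in the metr-1 mutant, where 6 of them fell and 1 rose, and of -0.05 (-0.37 to 0.03) in the pcca-1 mutant, where 9 fell and 4 rose. Both intervals met a bound of -0.5, but members went both ways past the threshold: of the falls in the pcca-1 mutant all but that of wrt-4 are of cuticle collagens, a class that fell at large, while noah-1, mlt-8, wrt-10 and dpy-17 rose. Of these, dpy-17 is a cuticle collagen gene too, so the collagens among the moulting genes also went both ways. Wild-type levels up to 14.31 would also hide a small share of larvae. Males, moulting larvae, the age at harvest, which was not tested, and an effect of the genotypes on sperm cannot be told apart.

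Immune effectors were lower in the metr-1 than in the pcca-1 mutant, with a median of -0.58 (-1.04 to -0.23 over resampled genes). A single array as the cause is argued against, since leaving out each of the 6 mutant arrays gave medians from -0.64 to -0.47 and camera adjusted p from 2.7e-11 to 3.4e-09. A lower share of intestinal RNA in the metr-1 mutant stays open, because intestine markers differed by -0.13 (-0.40 to 0.02) with 6 lower and 2 higher. With an estimated correlation the immune list had an adjusted p = 0.15, so the shift beyond correlated genes is itself open. An effect of the genotypes and a change in intestinal RNA cannot be told apart.

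The genes pud-3 and pud-4 fell in both mutants, and in the metr-1 mutant to percentiles 35.5 and 8.72 of all genes. A loss private to the metr-1 strain would not account for the falls in the pcca-1 mutant, where pud-3 changed by -2.75 and pud-4 by -2.85. Those falls are part of the flagged pattern itself, so they are no separate test. A deletion or variant in the metr-1 strain at the 2 genes may still add to the fall there: of their near neighbours 1 was measured, Y19D10B.6 at 3.78 in wild type, and 0 lay above the median gene, so a lost stretch would not show. This and a stronger effect of the metr-1 genotype cannot be told apart.

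Other splits of the arrays were counted in fits of the 2 compared groups. For metr-1 against wild type, the real split gave 5769 genes and the highest other 0; at an unadjusted p under 0.05, limma gave 7204 and at most 472. For pcca-1 against wild type the values were 5644 and 0, with 7011 and at most 559 unadjusted. For metr-1 against pcca-1 they were 981 and 0, with 2820 and at most 1951 unadjusted. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes, which puts their difference into the spread within groups and lowers the counts. The counts of 0 therefore do not show how many genes unchanged groups would give. At an unadjusted p under 0.05 in limma, mixed splits of the metr-1 and pcca-1 arrays still gave up to 1951 and 1404 genes. Metr-1 replicate 3 correlated at 0.990 with pcca-1 replicate 1 and at 0.990 with metr-1 replicate 2. These arrays thus also differ along lines other than genotype, which limits the comparison of the mutants with each other.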

How the results depend on the processing

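The fit on genes with unique probe sets alone was chosen only after the data were seen. The counts of genes past the threshold for metr-1 against wild type, pcca-1 against wild type and metr-1 against pcca-1 stayed within 1.5 times under the other variance model, repeated quantile normalization, fits of the compared groups alone, the median of probe sets, all probe sets and removal of dim genes. With each array centred on its median the metr-1 count was 9876. Centring adds about the same shift to all genes, and it moved their median change from 0.04 to 0.21. Higher calls went from 3177 to 7539 and lower calls from 3044 to 2337. Why the array medians differed between genotypes was not tested. Array weights gave 9940 for metr-1 against wild type and 8805 for metr-1 against pcca-1, with weights from 0.217 to 54.4, so that this fit rests largely on metr-1 replicate 1, and the estimation of the weights stopped before it converged. Fewer genes tested, with unique probe sets alone, left 3992, 3305 and 852. Stricter thresholds lower counts by construction: at least 2-fold left 1471, 1187 and 400 genes, an overlap of 125 genes that rose in both, 797 that fell in both and 17 opposite, and an adjusted p under 0.01 left 758 for metr-1 against pcca-1. The metr-1 gene in its mutant missed with the other variance model (0.28, adjusted p = 0.061), quantile normalization (0.15, adjusted p = 0.17) and the 2 groups alone (0.28, adjusted p = 0.055), with 0.0015 to 0.17 over its alternatives; the cause was not tested.

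Camera with an estimated correlation passed 0, 0 and 0 lists, with 3, 5 and 6 at an unadjusted p under 0.05, and fry, which tests against no change, passed 13 for pcca-1 against wild type. The replicate numbers gave no clear sign of a pairing of the arrays: own number was the best partner in 3 of 9 cases, and deviations correlated at -0.38 to 0.20. Deviations from means of 3 arrays are too few to exclude a pairing. With the replicate block the gene counts were 5939, 4807 and 1152, and 14, 8 and 16 lists passed camera. Leaving out 1 array gave 5113 to 6556, 3999 to 5729 and 877 to 2211 genes, the last without metr-1 replicate 3. It gave 9 to 15, 7 to 12 and 14 to 17 lists, 9 without metr-1 replicate 2. It gave acdh-1 changes of 8.14 to 8.36 and 7.88 to 8.10, 0.21 to 0.35 for metr-1 and -5.04 to -4.82 for pcca-1. The overlap ran at 1440 to 2251 that rose, 1813 to 2193 that fell and 85 to 145 opposite genes, 85 without wild-type replicate 2 or 3, 95 without metr-1 replicate 1 and 93 without pcca-1 replicate 2. Of 7174 values of named genes under alternatives, 185 lost and 73 gained a call and 0 reversed in limma, and of 1209 list values 97 lost and 32 gained a call and 0 reversed in camera or fry. Several alternatives, such as the other variance model and the replicate block, leave the size of a gene's change as it is. A change of sign without a call in either fit was not counted as reversed. The counts of 0 reversed were thus largely fixed in advance and show little about robustness. Signal near the background limits small changes of dim genes.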

Other observations

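All gene classes and tests in this part were chosen only after the data were seen, by grouping genes with the same symbol prefix into 141 classes of at least 12 genes and running camera over them. The classes described are a choice, and others passed as well. In the metr-1 mutant 24 of 40 ttr genes fell and 1 rose, 14 of 26 npp genes rose, and 15 of 27 set genes rose and 1 fell. Camera gave these adjusted p = 4.8e-07, 4.4e-04 and 0.0038 (0.62, 0.62 and 0.48 with an estimated correlation). The shifts below are thus not particular to the classes named. Of 25 flp neuropeptide genes 18 fell in the metr-1 mutant, and of 58 nlp genes 29 (adjusted p = 1.5e-05 and 2.2e-06; adjusted p = 0.56 and 0.61 with an estimated correlation); nlp-26 fell by 3.21 (SE 0.26). In the pcca-1 mutant, 14 flp genes fell and 1 rose, and 23 nlp genes fell and 2 rose (adjusted p = 3.5e-05 and 0.0019; adjusted p = 0.60 and 0.83 with an estimated correlation), with nlp-26 at -2.32 (SE 0.26). Neuron markers fell as well, 14 of 26 in the metr-1 mutant, with 2 that rose, and 11 of 26 in the pcca-1 mutant. Camera gave adjusted p = 0.0029 and 2.1e-04 (0.39 and 0.26 with an estimated correlation), so less neuronal RNA in the mutants is not excluded. Of 18 vha genes, for subunits of the vacuolar proton pump, 13 fell in the metr-1 mutant, among them vha-5 by a change of -1.1 (SE 0.16), and 9 in the pcca-1 mutant, with vha-5 at -0.97 (SE 0.16). Their adjusted p was 2.2e-04 in the metr-1 and 0.0047 in the pcca-1 mutant (adjusted p = 0.56 and 0.68 with an estimated correlation). The actin 3' to 5' difference was 0.68 and 0.65 in the mutants against 0.44 in wild type, while Gapdh gave -0.17 and -0.04 against 0.04, and ubiquitin 3.68 and 3.72 against 3.72.

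In the metr-1 mutant 21 of 38 bath genes rose, among them bath-24 by 1.20 (SE 0.15), as did 13 of 19 Skp1-related skr genes, with 2 that fell and skr-15 at 1.75 (SE 0.15), and 18 of 34 vacuolar sorting vps genes, with vps-16 at 1.09 (SE 0.10). Camera gave adjusted p = 6.0e-06, 0.0023 and 2.7e-04 (adjusted p = 0.40, 0.56 and 0.48 with an estimated correlation). In the same mutant 20 of 24 oocyte and 11 of 26 mitotic germline genes rose, so a change in germline RNA is not excluded. In the pcca-1 mutant, 20, 13 and 13 of them rose, with bath-24 at 0.81 (SE 0.15), skr-15 at 1.71 (SE 0.15) and vps-16 at 0.76 (SE 0.10) (adjusted p = 1.4e-04, 2.8e-05 and 0.0028; adjusted p = 0.39, 0.48 and 0.48 with an estimated correlation). Related classes varied. In the metr-1 mutant 11 of 95 fbxb genes rose, 14 of 44 fbxc genes rose and 1 fell, 26 of 171 fbxa genes rose and 28 fell, and 1 of 47 math genes rose and 10 fell (adjusted p = 0.032, 0.010, 0.69 and 0.091; adjusted p = 0.48, 0.48, 0.89 and 0.62 with an estimated correlation). Of all 17118 genes 3177 rose in that mutant, a larger share than among the fbxb, fbxa and math genes. In the pcca-1 mutant 19, 14, 36 and 3 rose, and of the fbxa and math genes 13 and 4 fell (adjusted p = 0.011, 0.0047, 0.28 and 0.88; adjusted p = 0.48, 0.46, 0.84 and 0.98 with an estimated correlation). Between the mutants, 13 of 32 carboxylesterase genes (cest) and 9 of 30 short-chain dehydrogenase genes (dhs) were lower in the metr-1 mutant, with cest-1.2 at -2.64 (SE 0.23) and dhs-2 at -1.86 (SE 0.12). Their adjusted p was 2.7e-07 and 2.0e-04 (adjusted p = 0.77 and 0.77 with an estimated correlation). Intestine markers were lower there as well, 6 of 22 with 2 higher (adjusted p = 0.0020; adjusted p = 0.36 with an estimated correlation), so less intestinal RNA in the metr-1 mutant is not excluded.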
